A study of Homo sapiens with 48 samples.

How the data were processed

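Peripheral blood monocytes were purified on CD14 beads, cultured for 5 days with GM-CSF at 500 U/ml and IL-4 at 1000 U/ml, and rested for 1 day in medium without cytokine, per the labels. Cells of each of 4 donors were then left untreated or given IL-6 or IL-10 at 10 ng/ml. Total RNA was labelled with biotin and hybridised to Illumina HT-12 version 4 arrays, per the labels and the platform record. The submitters' processing notes name BeadStudio without a version; how background and normalization were set in it is not given in the sources used here.

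The deposited table without normalization holds, per the file headers, a signal column for each of the 48 arrays, whose unit is intensity on a linear scale, and beside it a detection column, whose unit is a p-value for detection. The authors' processed values are intensity on a linear scale as well. Their medians lay between 119.715 and 119.799 on all arrays, a spread that quantile normalization across arrays gives, although the method is not given in the sources used here. Signal columns were matched to samples through the deposited key, which pairs array names with samples. As a check, the rank correlation was 1 between an array and its own processed column and at most 0.896 with that of any other sample. No column was left without a sample. The highest rank correlation between any pair of arrays was 0.896, so no array was entered more than once. Each chip held the 12 samples of 1 donor, and each group sat at the same position on all 4 chips. Position on the chip therefore cannot be separated from the group, nor the chip from the donor.

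Of 47323 probes, 30113 carried 1 gene symbol, 8 carried several and 17202 had no name. Symbols of 30074 probes were matched to current ones by gene identifier and 0 changed. A probe was kept when its detection p was under 0.01 on at least 4 of the 48 arrays, which left 17276 probes, 13626 of them named and 3650 not. Signals were background corrected and quantile normalized with negative control statistics inferred from the detection p-values (neqc in limma 3.58.1) and placed on the log2 scale. The probe with the highest mean stood for a gene with several, which left 10412 genes.

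limma fitted a mean for each of the 12 groups with the donor as a fixed block, leaving 33 residual degrees of freedom. Moderated p-values from empirical Bayes were adjusted by Benjamini-Hochberg over all genes within each comparison, and a gene was called at adjusted p under 0.05. The donor block departs from the default of a fit without it and was chosen before the data were examined, because the cells of each donor were divided over all conditions. For the comparisons of groups and the genes shared by both cytokines, the count of called genes without the block is also given where it differs. Whether samples of the same donor number resembled each other was checked in the data. Deviations from the group mean correlated by at least 0.190 (median 0.592) between samples of the same donor and by at most 0.156 between samples of different donors and groups. The best partner of 48 of 48 samples was of the same donor. Each chip held 1 donor, so a chip effect alone would give the same pattern, and removing group means lowers correlations between donors. The check therefore cannot tell donor from chip. Replicate numbers 1 to 4 in the labels are the donor numbers used here.

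Gene lists and the rule for naming genes were fixed before the data were examined. In each comparison the rule took, among called genes with the same sign in all 4 donors, the 5 with the largest and the 5 with the most negative log2 difference. It took 10 and 10 for untreated 12 h against 0 min and for IL-10 against untreated cells at 12 h. It added up to 4 members of a described list with the largest absolute difference and, always, SOCS3, BCL3, STAT3, IL10RA, IL6R, IL6ST, CD163, CD14 and CD1A, and genes so named could be followed in other comparisons. The text leaves out some of the genes that the rule took. In the receptor, JAK and STAT genes and the markers of other cells, further members were given by value. XIST, Y-linked genes and unnamed probes were never named.

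Of 26 lists, 1 is not reported here, and the others were STAT3 immediate targets and feedback, IL-6 and IL-10 receptors with JAKs and STATs, IL-10-associated macrophage genes, type I interferon-stimulated genes, MHC class II presentation, dendritic cell maturation, dendritic cell identity, IL-4-induced myeloid genes, monocyte markers, NF-kB inflammatory cytokines and chemokines, immediate early genes, cholesterol synthesis, LXR targets and lipid efflux, heat shock response, unfolded protein and integrated stress response, metallothioneins, hypoxia and glycolysis, cell cycle, ribosomal proteins, and markers of T cells, NK cells, B cells, platelets, erythroid cells and neutrophils. Lists with 5 or more measured members, 21 of the 26, were tested with camera at its preset correlation of 0.01 and Benjamini-Hochberg over 399 tests, and again with an estimated correlation. Members called were counted with p-values adjusted over all genes and over the list alone.

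Alternatives fixed before the data were examined were normexp background correction with an offset of 50 and quantile normalization, the authors' processed values, no filter on dim probes, a stricter filter that kept 13761 probes, the fit without the donor block, and each donor left out in turn. A fit with array quality weights was added after the arrays were seen to differ in detected probes. Taking the chip as a random block was not run, because chip and donor are the same here.

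As a self-test, the comparison of IL-10 with untreated samples at 12 h was simulated with 200 of 10412 genes changed. The spread of each gene was the moderated one from the fit to all groups, not that of these samples alone. Noise was drawn as independent and normal, with additive donor effects. The recovery rates therefore hold for these simulated data and need not hold at the actual spread of that comparison. The fit recovered 100% of genes changed by 2 on the log2 scale, 94% at 1, 42% at 0.5 and 98% at −1, with 7.22% of the calls false. Software was R 4.3.3, limma 3.58.1, the data.table package at 1.17.8, Python 3.11.15 and matplotlib 3.10.9. Probes without a gene name were tested apart, and only their count is given.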

Results

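Expression was measured in monocyte-derived dendritic cells from 4 donors that had been left untreated or given 10 ng/ml IL-6 or IL-10. CD14+ monocytes had been differentiated for 5 days in GM-CSF and IL-4 and rested for 1 day without cytokine before treatment. Each cytokine was sampled at 45 min, 2 h, 4 h, 8 h and 12 h, and untreated cells at 0 min and at 12 h, giving 12 groups of 4 donors and 48 arrays. Between 12631 and 15522 probes per array were detected, and 10412 genes were tested. Differences are log2 differences ± SE from 1 fit to all 48 arrays with n = 4 donors per group, and p-values are adjusted. Unless another number of donors is given, a named difference that was called had the same direction in 4 of 4 donors. No fold is given where the dimmer group was detected on fewer than 4 of its arrays, and the log2 difference there rests partly on levels near background. Untreated cells were sampled only at 0 min and 12 h, so differences from untreated 0 min at other times hold any effect of time and handling as well as that of the cytokine.

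The first principal component, with 33.2% of the variance left after donor means were removed, placed untreated cells at −25.5 at 0 min and 19.9 at 12 h, and cells with IL-6 for 12 h at 20.2. The second, with 14.0%, moved with time as well as cytokine. From 45 min to 12 h its means were −5.68, 17.2, 22.5, 11.3 and 5.58 with IL-10 and −7.35, 6.31, 2.28, −8.51 and −14.9 with IL-6, against −12.1 at 0 min and −16.7 at 12 h in untreated cells. At 45 min the means of both cytokine groups lay near untreated 0 min on the first component, at −27.8 with IL-10 and −25.4 with IL-6.

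**Figure D1:**
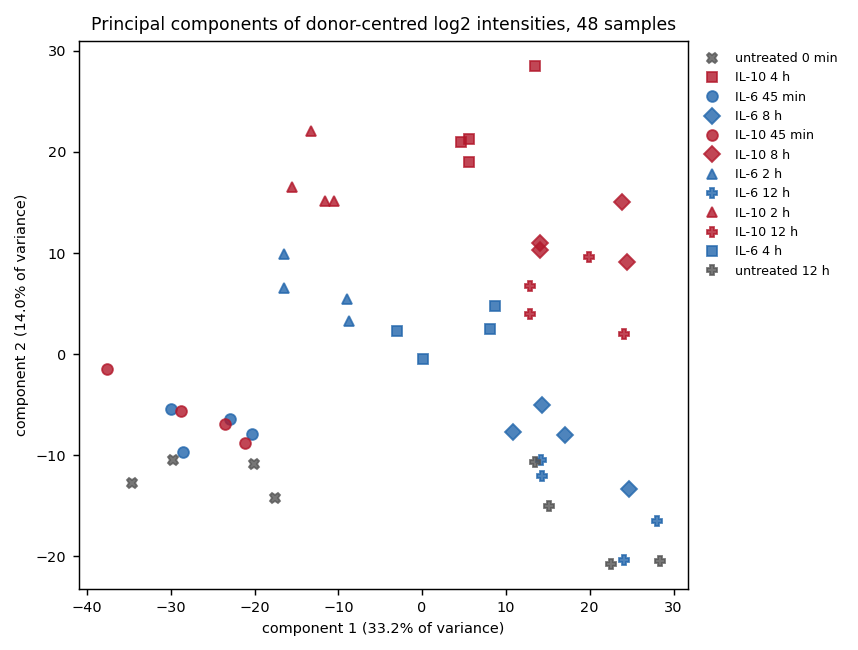
Principal components of the 48 samples after each donor's mean was removed, with component 1 (33.2% of variance) on the horizontal and component 2 (14.0%) on the vertical axis, in component score units. Each point is 1 sample, coloured by treatment and marked by time; the mean of untreated cells moved along component 1 from −25.5 at 0 min to 19.9 at 12 h, and IL-10 samples at 2 h and 4 h lay highest on component 2.

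Untreated cells changed strongly over 12 h without any added cytokine. OCSTAMP, a membrane protein of cell fusion, rose by 3.91 ± 0.45 (n = 4, adjusted p = 2.08e-08), and the macrophage growth factor gene CSF1 rose by 3.42 ± 0.37 (adjusted p = 5.69e-09). The chemokine genes CCL7 (3.45 ± 0.41) and CCL3 (3.27, adjusted p = 1.44e-09) rose too, as did TIMP3 (3.34 ± 0.34). Rises were also seen for the cystine transporter gene SLC7A11 (3.10, adjusted p = 4.6e-07), GEM (3.03) and the tight junction gene CLDN1 (3.41 ± 0.51, adjusted p = 1.97e-06, 0.0802 without the donor block). Other detected GEM probes were at 2.294 and 0.196. CCL3L1 (3.45 ± 0.33) and CCL4L1 (3.29) also rose, but their probes may cross-hybridise with CCL3 and CCL4, so which copy changed is uncertain. NFE2, a transcription factor gene of the myeloid line, fell by −4.10 ± 0.43 (adjusted p = 3.98e-09), and SLC40A1, the iron exporter ferroportin, fell by −3.35 ± 0.34 (adjusted p = 1.83e-09). ID3 (−2.62, adjusted p = 8.91e-07), FAM117B (−2.47) and GIMAP7 (−2.27) fell, the last within a family of similar sequences. Metallothionein genes fell together, MT1H by −3.33 ± 0.52, MT1X by −3.12 ± 0.57, MT1G by −2.80, MT1E by −2.57 and MT1F by −2.37, and here too the family members cannot be told apart with certainty.

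In all, 3532 genes differed between untreated 12 h and 0 min, 1428 higher and 2104 lower, with 1809 called without the donor block and 3357, 2799, 2246 and 2948 without donor 1, 2, 3 and 4. The monocyte receptor gene CD14 fell 3.05-fold (−1.61 ± 0.22, adjusted p = 5.53e-07, 0.124 without the block) and CD163 fell (−0.64, adjusted p = 0.00034, 0.625 without the block). SOCS3 rose by 1.00 (adjusted p = 0.000594) and BCL3 by 0.45 (adjusted p = 0.00303, 0.274 without the block). STAT3 was called with 0.31 (adjusted p = 0.0376), a call that ended without the block (0.202), without donor 1 (0.297), donor 3 (0.118) or donor 4 (0.0914), and with no filter on dim probes (0.0589).

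Gene lists gave the 12 h drift a stress and maturation character. Of 15 genes of the unfolded protein and integrated stress response, 13 rose (13 adjusted over the list alone), among them PSAT1 (2.03), ASNS (1.86, adjusted p = 7.53e-09) and TRIB3 (1.78), with a list test adjusted p = 2.46e-11 (0.000456 with an estimated correlation). Dendritic cell maturation genes rose, 16 of 24 (16 adjusted over the list alone, adjusted p = 3.74e-11, 0.00737 with an estimated correlation), led by TRAF1 (2.05, adjusted p = 1.41e-08), ICAM1 (1.61), CD40 (1.47, adjusted p = 3.47e-07) and CD80 (1.40). NF-kB inflammatory cytokine and chemokine genes rose in 21 of 24 (21 adjusted over the list alone), with a list adjusted p = 7.83e-12 that became adjusted p = 0.114 with an estimated correlation. All 7 metallothioneins fell (7 adjusted over the list alone, median −2.57, adjusted p = 4.44e-05, but adjusted p = 0.305 with an estimated correlation). Immediate early genes were higher in 7 of 14 (7 adjusted over the list alone), ATF3 by 2.59 (adjusted p = 6.3e-12), with adjusted p = 0.00418 for the list, or adjusted p = 0.483 with an estimated correlation. Hypoxia and glycolysis genes included ADM (1.59, adjusted p = 1.11e-07), ENO2 (1.24) and VEGFA (0.99) among 7 of 20 that rose (7 adjusted over the list alone, adjusted p = 0.00353, adjusted p = 0.634 with an estimated correlation).

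Over the untreated 12 h cholesterol synthesis had 3 of 14 genes higher (3 adjusted over the list alone), INSIG1 by 1.70 (adjusted p = 5.7e-09), with a list adjusted p = 0.0223 that was 0.158 without donor 1 and adjusted p = 0.426 with an estimated correlation. Ribosomal protein genes had 6 of 18 lower (6 adjusted over the list alone), RPL5 by −0.44 (adjusted p = 0.00134), with a list adjusted p = 0.0348 that was 0.156 without donor 3 and adjusted p = 0.426 with an estimated correlation. In MHC class II presentation 5 of 17 were lower (5 adjusted over the list alone, list adjusted p = 0.318), RFX5 by −0.59 (adjusted p = 8.58e-06). Cell cycle had 2 of 10 lower (2 adjusted over the list alone, list adjusted p = 0.396), with PCNA at −0.57 (adjusted p = 8.01e-05). Among 6 neutrophil markers MMP9 was higher by 1.10 and CSF3R lower by −0.76, with 1 higher and 2 lower (the same counts adjusted over the list alone, list adjusted p = 0.731).

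Signalling feedback and immediate early genes were higher after 45 min with IL-10 than in untreated cells at 0 min. SOCS3, an inhibitor of JAK and STAT signalling, rose by 4.71 ± 0.22 (26.3-fold, n = 4, adjusted p = 2.58e-18). GADD45B rose by 3.40 ± 0.17 (10.6-fold, adjusted p = 2.58e-18), the activation marker CD69 by 4.49 ± 0.42 (adjusted p = 1.08e-09) and IL6 by 3.21 ± 0.45 (9.22-fold, adjusted p = 6.85e-06, 0.0837 without the block). FOSB rose at least 7.72-fold (3.73 ± 0.35, adjusted p = 1.08e-09), its level in untreated cells being not well above background. Such bounds compare the mean of the bright group with the mean, over the dim arrays, of the higher of the lowest detected signal on the array and the probe's own signal. BCL3 rose by 1.07 ± 0.12 (adjusted p = 5.22e-08, 0.0658 without the block), while STAT3 itself was at 0.41 ± 0.12 (adjusted p = 0.0729). RSRP1 (−1.30 ± 0.19, adjusted p = 1.79e-05) and the splicing kinase gene CLK1 (−1.17 ± 0.16, adjusted p = 2.77e-06) fell. ADM (−0.85, adjusted p = 0.0155) was not called without the block (0.83), donor 2 (0.61) or donor 3 (0.118). RSBN1 (−0.82, adjusted p = 0.00737) was not called without the block (0.109), donor 1 (0.0585) or donor 2 (0.676). ZNF627 (−0.80, adjusted p = 0.0235) was not called without the block (0.189), donor 1 (0.0749), donor 2 (0.833) or donor 4 (0.068), or with array quality weights (0.055). Altogether 140 genes were called, 87 higher and 53 lower, against 42 without the block and 87, 54, 71 and 74 without donor 1, 2, 3 and 4.

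CD69, SOCS3, FOSB and IL6 were also among the largest rises after 45 min with IL-6. CD69 rose by 4.68 ± 0.42 (n = 4, adjusted p = 4.86e-10), SOCS3 by 4.12 ± 0.22 (17.4-fold, adjusted p = 2.16e-16) and NFKBIZ, a regulator of NF-kB target genes, by 3.16 ± 0.33 (8.96-fold, adjusted p = 1.11e-08). FOSB rose at least 8.44-fold (3.86 ± 0.35, adjusted p = 4.86e-10) from a level not well above background, and IL6 by 3.09 ± 0.45 (8.50-fold, adjusted p = 1.43e-05, 0.119 without the block). BCL3 rose by 1.03 ± 0.12 (adjusted p = 1.26e-07, 0.0977 without the block), and STAT3 was at 0.31 ± 0.12 (adjusted p = 0.445). RSRP1 (−1.14, adjusted p = 0.000194) and CLK1 (−1.11, adjusted p = 6.8e-06) fell. ADM (−0.96, adjusted p = 0.00496) was not called without the block (1), donor 1 (0.0688) or donor 3 (0.0626). ZNF606 was lower by −0.81 (at least 1.27-fold, adjusted p = 0.0277) and with IL-6 was not well above background; the call ended with no filter on dim probes (0.0563), and without the block (0.266), donor 2 (0.429), donor 3 (0.218) or donor 4 (0.0771). In total 105 genes were called, 78 higher and 27 lower, against 40 without the block and 72, 67, 50 and 57 without donor 1, 2, 3 and 4.

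STAT3 targets and inflammatory genes rose together at 45 min under both cytokines. Of 22 STAT3 immediate targets and feedback genes, 5 of them also in another list, 10 rose with IL-10 (12 adjusted over the list alone, adjusted p = 5.4e-26) and 9 with IL-6 (11 adjusted over the list alone, adjusted p = 1.26e-31). PIM1 rose by 2.45 with IL-10 (adjusted p = 5.79e-08) and 2.18 with IL-6 (adjusted p = 8.06e-07), and GADD45B by 2.99 with IL-6 (adjusted p = 2.16e-16). Of 14 immediate early genes 9 rose with IL-10 (12 adjusted over the list alone, adjusted p = 8.9e-25), among them DUSP2 (2.22, adjusted p = 3.2e-05) and ZFP36 (1.70, adjusted p = 4.25e-10), and 10 with IL-6 (12 adjusted over the list alone, adjusted p = 3.63e-39). NF-kB inflammatory genes rose in 9 of 24 with IL-10 (10 adjusted over the list alone), including NFKBIZ (2.97 ± 0.33, adjusted p = 5.24e-08) and ICAM1 (1.34, adjusted p = 5.41e-06). The list adjusted p = 2.74e-10 became adjusted p = 0.163 with an estimated correlation. With IL-6, 10 of 24 rose (11 adjusted over the list alone, adjusted p = 2.57e-23, adjusted p = 0.0134 with an estimated correlation).

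At 45 min no gene separated the cytokines. SOCS3 was 0.59 ± 0.22 higher with IL-10 than with IL-6 in 3 of 4 donors (n = 4, adjusted p = 1), a value that rested on donor 2, since it was 0.06 without that donor. BCL3 differed by 0.04 with that sign in 3 of 4 donors, and STAT3 by 0.10 in 2 of 4 (adjusted p = 1 for each). With limma 0 genes were called, and 242 had an unadjusted p under 0.05 where 521 would be expected by chance. The count stayed 0 with normexp and quantile normalization, with the authors' processed values, with other probe filters, without the donor block, with array quality weights and with any donor left out. The 95% interval lay within a 2-fold difference for 10340 genes (99.3%). The STAT3 target list leaned toward IL-10 (0 called, 0 adjusted over the list alone, adjusted p = 0.0481), but with adjusted p = 0.243 with an estimated correlation, 0.0681 without the block, and 0.0774, 0.862 and 0.0649 without donor 1, 2 and 3. The NF-kB inflammatory list leaned toward IL-6 (median −0.24, 0 called, 0 adjusted over the list alone, adjusted p = 0.00249, but adjusted p = 0.634 with an estimated correlation).

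More genes differed from untreated 0 min after 2 h and 4 h with IL-10 than after 45 min. At 2 h the glutamate transporter gene SLC1A3 rose by 4.63 ± 0.27 (24.7-fold, n = 4, adjusted p = 5.76e-16) and PIM1 by 3.63 ± 0.27 (adjusted p = 7.71e-13). NAMPT, of NAD synthesis, rose by 3.44 ± 0.22 (10.8-fold, adjusted p = 1.02e-14). SOCS3 stayed high (4.04 ± 0.22, adjusted p = 1.79e-16), BCL3 reached 2.24 ± 0.12 (4.73-fold, adjusted p = 8.59e-17), and STAT3 rose by 0.73 ± 0.12 (adjusted p = 1.25e-05). EGR3 rose at least 6.21-fold (3.56 ± 0.48, adjusted p = 5.18e-07) from a level not well above background. FOXQ1 fell by −2.73 ± 0.20 (6.64-fold, adjusted p = 4.17e-13) and the adenosine receptor gene ADORA3 by −2.04 ± 0.20 (adjusted p = 6.9e-10). HHEX fell by −1.80 (adjusted p = 6.41e-09), ZFP36L2 by −1.74 (adjusted p = 1.28e-07) and CITED2 by −1.74 (adjusted p = 2.88e-07). At 4 h SLC1A3 was up 33.4-fold (5.06 ± 0.27, adjusted p = 3.74e-17), NAMPT by 4.06 (adjusted p = 6.33e-17) and the amino acid transporter gene SLC16A10 by 4.01 ± 0.39 (adjusted p = 2.31e-10). SOCS3 was up by 3.45 ± 0.22 (adjusted p = 1.37e-14), BCL3 by 1.89 (adjusted p = 4.49e-15) and STAT3 by 1.39 (adjusted p = 1.1e-11). TNIP3, an inhibitor of NF-kB activation, rose at least 6.70-fold at 4 h (3.69 ± 0.36, adjusted p = 2.88e-10), from a level not well above background. ADORA3 (−2.82, adjusted p = 1.3e-13), ADORA2B (−2.29, adjusted p = 2.74e-11), ZFP36L2 (−2.18), FAM117B (−2.12) and RTKN (−2.01) fell. Counts were 1966 at 2 h (818 higher, 1148 lower; 939 without the block; 1507, 1293, 1456 and 1416 without donor 1, 2, 3 and 4). At 4 h the count was 3548 (1365 higher, 2183 lower; 1966 without the block; 2592 to 3005 with a donor left out).

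At 8 h and 12 h with IL-10 SLC1A3 and SLC16A10 stayed high, and SLC40A1 and JUP fell. SLC1A3 was up by 4.51 at 8 h (adjusted p = 2.76e-15) and 4.32 at 12 h (adjusted p = 7.27e-15), and SLC16A10 by 4.28 and 3.90, n = 4. The tubulin gene TUBB3 was up by 3.59 and 3.46 (adjusted p = 3.7e-15 at 12 h) and SOCS3 by 3.51 and 3.06 (adjusted p = 3.65e-13 at 12 h). THBS1 rose by 3.43 at 8 h (adjusted p = 5.22e-08, 0.0508 without the block) and 3.11 at 12 h (adjusted p = 4.27e-07, 0.092 without the block), and LILRA5 by 3.33 at 12 h (adjusted p = 7.51e-15). Other detected LILRA5 probes were at 1.209 and 2.453 at 12 h. SLC40A1 fell by −3.89 at 8 h (adjusted p = 2.41e-11) and by −4.32 ± 0.34 at 12 h (adjusted p = 1.95e-12), JUP by −2.81 and −3.10 (adjusted p = 2.08e-08 at 12 h) and ADORA3 by −2.58 and −2.77. A second detected JUP probe was only at −0.47 and −0.34, so the size of the JUP fall depends on the probe. GPR34 (−2.43) and ADORA2B (−2.36) fell at 8 h, and GPBAR1 (−2.68) and OAF (−2.31) at 12 h. BCL3 stood at 1.65 and 1.35, and STAT3 at 1.31 and 1.01 (adjusted p = 1.36e-08 at 12 h). CD163, a scavenger receptor gene, rose by 0.82 at 8 h and 1.02 at 12 h (adjusted p = 2.25e-07), against 0.488 and 0.407 without the block. The lipid-presenting molecule gene CD1A fell by −0.75 and −1.15 (adjusted p = 2.63e-08 at 12 h), against 0.344 and 0.142 without the block. Counts were 3887 at 8 h (1538 higher, 2349 lower; 2156 without the block; 2722 to 3541 with a donor left out). At 12 h the count was 3386 (1382 higher, 2004 lower; 1687 without the block; 2349 to 2873 with a donor left out).

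With IL-6, SOCS3 stood less far above untreated 0 min at 2 h and 4 h than at 45 min. At 2 h the transcription factor gene EGR3 rose at least 8.98-fold (4.09 ± 0.48, n = 4, adjusted p = 1.15e-07) from a level not well above background. SLC1A3 rose by 3.42 ± 0.27 (10.7-fold, adjusted p = 9.55e-12), NR4A2 by 3.25 ± 0.46 (adjusted p = 4.44e-06). GEM rose by 3.10 ± 0.46 (adjusted p = 9.56e-06) and IRAK2 by 2.89 ± 0.38 (adjusted p = 1.06e-06). Other detected GEM probes were at 2.385 and 0.394 at 2 h, and at 2.615 and 0.282 at 4 h. SOCS3 was up by only 0.91 ± 0.22 at 2 h (adjusted p = 0.00476, 0.066 with normexp and quantile normalization and 0.141 with the authors' processed values) and by 1.39 at 4 h (adjusted p = 1.85e-05). BCL3 rose by 1.60 ± 0.12 at 2 h (adjusted p = 3.28e-12) and 1.05 at 4 h, and STAT3 by 0.58 (adjusted p = 0.000576) and 0.70. ZNF792 (−1.39, adjusted p = 1.15e-07), CITED2 (−1.31, adjusted p = 8.85e-05) and the glucose transporter gene SLC2A1 (−1.45, adjusted p = 0.00986, 0.174 without donor 2) fell at 2 h. GIMAP7 (−1.55, adjusted p = 0.000206, 0.115 without the block) and GIMAP1 (−1.38, adjusted p = 0.000762) fell too, with uncertain probe identity. At 4 h GEM (3.49, adjusted p = 7.05e-07), CCL7 (3.02, adjusted p = 1.05e-06), CCL4L1 (3.21) and CCL3L1 (3.15) rose, and EGR3 rose at least 4.81-fold (3.19). NFE2 (−1.86, adjusted p = 0.00158), CD1D (−1.67, adjusted p = 2.19e-05), FAM117B (−1.59), GIMAP7 (−1.60, adjusted p = 0.0597 without the block) and the sterol exporter gene ABCG1 (−1.50, adjusted p = 5.42e-05, 0.0706 without the block) fell. A second detected ABCG1 probe was at −1.30, but a further one was at 0.21. Counts were 1218 at 2 h (552 higher, 666 lower; 478 without the block; 943, 666, 854 and 695 without donor 1, 2, 3 and 4). At 4 h there were 2412 (983 higher, 1429 lower; 969 without the block; 2166, 1339, 1845 and 1523 without those donors).

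With IL-6 for 8 h and 12 h, OCSTAMP and CCL7 rose and NFE2 and SLC40A1 fell against untreated 0 min. OCSTAMP rose by 3.53 at 8 h and 3.48 ± 0.45 at 12 h (n = 4, adjusted p = 1.77e-07), CCL7 by 3.44 and 3.41, CCL3L1 by 3.34 and 3.27 and, at 8 h, CCL4L1 by 3.33 and SLC16A10 by 3.46. At 12 h CSF1 rose by 3.32 (adjusted p = 1.03e-08) and CLDN1 by 3.20 (adjusted p = 5.53e-06, 0.105 without the block). NFE2 fell by −3.55 at 8 h and −4.09 ± 0.43 at 12 h (adjusted p = 4.67e-09). SLC40A1 fell by −2.90 and −3.91 (adjusted p = 7.73e-11) and ID3 by −2.21 and −2.88. GPR34 fell by −2.03 at 8 h. MT1H fell by −1.997 at 8 h (adjusted p = 0.00287, 0.0683 without donor 2) and −3.20 at 12 h, and MT1G by −2.58 at 12 h. SOCS3 stayed at 1.5 (adjusted p = 2.56e-06) and 1.51 (adjusted p = 1.86e-06), BCL3 at 0.82 and 0.77, and STAT3 at 0.67 and 0.43 (at 12 h adjusted p = 0.00454, 0.0715 without the block and 0.144 without donor 1). CD14 fell by −1.20 at 12 h (adjusted p = 5.67e-05, 0.276 without the block) and CD163 by −0.76 (adjusted p = 3.87e-05, 0.557 without the block). Counts were 3362 at 8 h (1371 higher, 1991 lower; 1640 without the block; 2267 to 3190 with a donor left out). At 12 h there were 3438 (1406 higher, 2032 lower; 1763 without the block; 3338, 2561, 2161 and 2892 without donor 1, 2, 3 and 4).

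**Figure D2:**
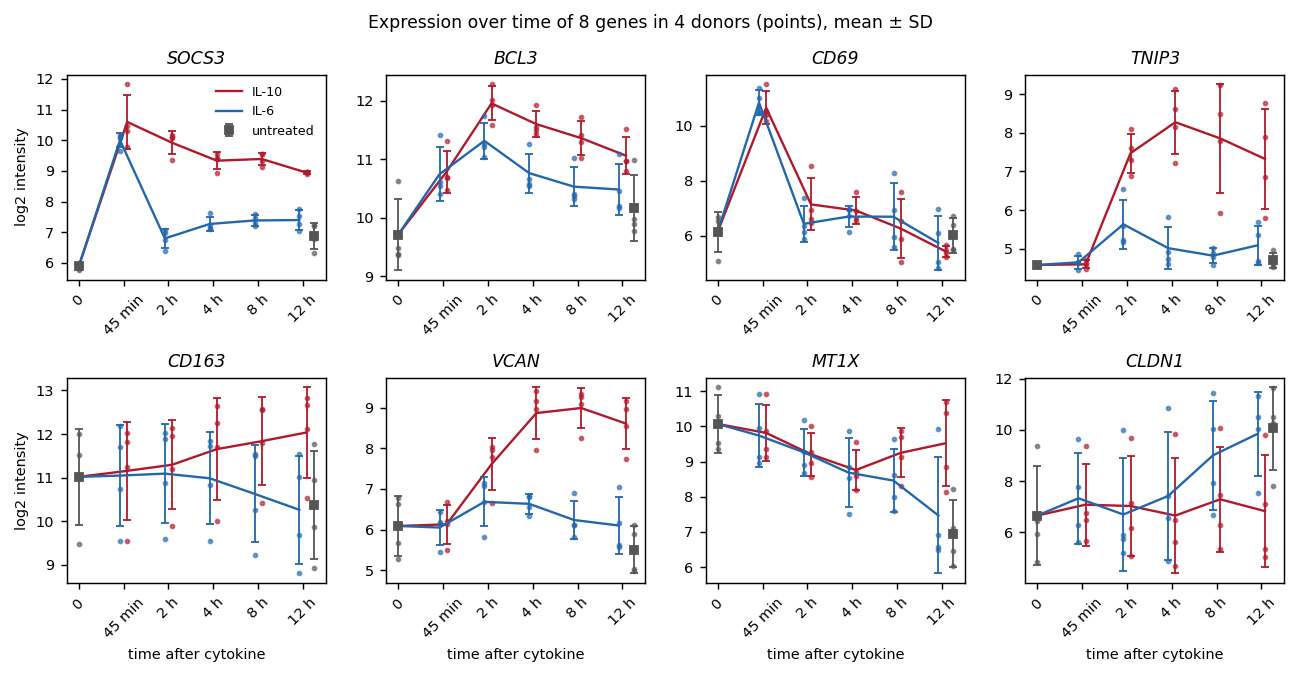
Levels of 8 genes (SOCS3, BCL3, CD69, TNIP3, CD163, VCAN, MT1X and CLDN1) in log2 intensity on the vertical axis against time, with the sampled times evenly spaced on the horizontal axis. Points are donors and lines with bars are means ± SD of 4 donors for IL-10 (red), IL-6 (blue) and untreated cells (grey squares at 0 and 12 h), and SOCS3 reached 4.71 above untreated 0 min at 45 min with IL-10 and held 3.06 at 12 h, while with IL-6 it was at 0.91 by 2 h.

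The sets of genes called with IL-6 and IL-10 overlapped heavily at every time. Each set was called against untreated 0 min and so holds change with time in culture, which untreated cells showed in 3532 genes by 12 h. IL-6 at 12 h differed from untreated 12 h in 0 genes, so the sharing at 12 h cannot be read as a response to both cytokines. Counted with the same direction in both against untreated 0 min, 91 genes such as SOCS3, CD69 and NFKBIZ were shared at 45 min, 1011 at 2 h, 1916 at 4 h, 2592 at 8 h and 2308 at 12 h. Those were 86.7%, 83%, 79.4%, 77.1% and 67.1% of the IL-6 calls, and 0, 0, 3, 15 and 22 genes went opposite ways. Independent sets would have shared 0.789, 117, 428, 652 and 578. With IL-10 fitted on 2 donors and IL-6 on the other 2, so that no control was shared, the mean shared counts were 18.8, 149, 460, 778 and 721. Each of these fits held fewer treated and untreated samples. Their counts are therefore not comparable with those of 4 donors or with the values for independent sets, which rest on 4 donors. Without the donor block they were 34, 400, 793, 1235 and 1104. Without donor 1, 2, 3 and 4 the shared counts were 62, 50, 45 and 52 at 45 min, 758, 539, 684 and 571 at 2 h, 1700, 1083, 1385 and 1233 at 4 h, 2416, 1713, 1698 and 1974 at 8 h, and 2056, 1758, 1375 and 1869 at 12 h. Across genes, which are not independent replicates, the differences from untreated 0 min correlated with r between 0.805 and 0.845 and covaried by 0.044 to 0.206, where the shared controls alone gave r near 0.501 and a covariance near 0.014. With the cytokines fitted on different donors, so that no control was shared, r was 0.475 at 45 min, 0.631 at 2 h, 0.646 at 4 h, 0.698 at 8 h and 0.663 at 12 h. The value of 0.501 is not a reference for these r, which share no control and rest on 2 donors for each cytokine. At 45 min the covariance in these fits was 0.035. The r near 0.501 came from simulated groups without any change over time, whereas the observed values hold that change.

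**Figure D3:**
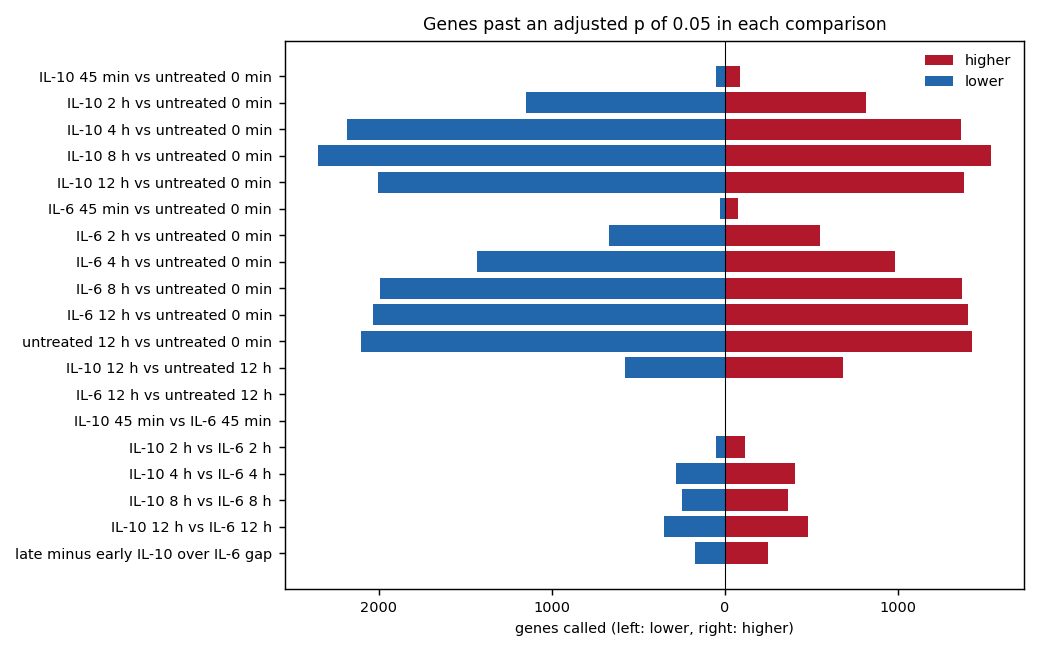
Number of genes called in each of the 19 comparisons, lower to the left (blue) and higher to the right (red), as horizontal bars of gene counts. IL-10 at 12 h differed from untreated 12 h in 1262 genes and IL-6 in 0.

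Against untreated cells of the same age, monocyte and macrophage genes were higher after 12 h with IL-10. In this comparison rises and falls are differences from untreated 12 h and need not be changes from 0 min. DHRS2 rose by 3.45 ± 0.25 (10.9-fold, n = 4, adjusted p = 6.73e-13, 0.128 without the block) and the matrix proteoglycan gene VCAN by 3.11 ± 0.26 (adjusted p = 2.79e-11). OLFML2B rose by 3.10 ± 0.25 (adjusted p = 1.01e-11) and FPR1, a receptor for bacterial peptides, by 2.88 ± 0.24 (adjusted p = 2.74e-11). LILRA5 (2.45 ± 0.21, adjusted p = 3.31e-11), PRRX2 (2.41 ± 0.22, adjusted p = 1.2e-10) and MT1X (2.57 ± 0.57, adjusted p = 0.00156, 0.0566 without donor 2) rose as well. Other detected LILRA5 probes were at 1.161 and 1.948. TNIP3 rose at least 3.07-fold (2.62 ± 0.36, adjusted p = 1.2e-06) and ARNT2 at least 3.25-fold (2.62 ± 0.34, adjusted p = 4.61e-07). CEMIP rose at least 2.57-fold (2.44 ± 0.54, adjusted p = 0.0013), and all 3 were not well above background in untreated cells. CD163 rose by 1.65 ± 0.14 (3.15-fold, adjusted p = 1.68e-11, 0.333 without the block) and CD14 by 1.42 ± 0.22 (2.68-fold, adjusted p = 1.2e-05, 0.412 without the block). Against untreated 0 min, CD14 with IL-10 at 12 h was at −0.187. SOCS3 was 2.06 ± 0.22 higher (adjusted p = 1.16e-08), STAT3 0.70 ± 0.12 (adjusted p = 3.63e-05) and BCL3 0.90 (adjusted p = 5.24e-07, 0.0626 without the block). IL10RA (0.05, adjusted p = 0.865) and IL6ST (−0.07, adjusted p = 0.823), with these signs in 3 of 4 donors and receptor chain genes for IL-10 and IL-6, passed in 0 of the 19 comparisons. IL6R passed only with IL-10 at 8 h against untreated 0 min (0.89, adjusted p = 0.00312).

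Genes lower with IL-10 than in untreated cells at 12 h included several that had risen in culture. The falls given here are differences from untreated 12 h and need not be falls from 0 min. Against untreated 0 min, BCL2 was at 0.213 and IFNLR1 at −0.112 with IL-10 at 12 h. In untreated cells at 12 h they were at 1.88 and 1.52. CLDN1 fell by −3.23 ± 0.51 (n = 4, adjusted p = 1.24e-05, 0.271 without the block) and TIMP3 by −1.73 (3.31-fold, adjusted p = 0.000383, 0.196 without the block). The growth factor gene HBEGF fell by −1.95 (3.86-fold, adjusted p = 0.00597, 0.162 without the block) and GAL by −1.68 (adjusted p = 0.00379, 0.402 without the block). BCL2, an inhibitor of cell death, fell by −1.67 ± 0.23 (3.18-fold, adjusted p = 9.22e-07) and the interferon lambda receptor gene IFNLR1 by −1.63 ± 0.26 (adjusted p = 1.21e-05). A second detected IFNLR1 probe was at −0.73. TNC (−1.60, adjusted p = 0.451 without the block) and DPYSL3 (−1.60, adjusted p = 0.00184) fell, and CLEC5A fell at least 2.11-fold (−2.003 ± 0.43, adjusted p = 0.00108, 0.0599 without the block) to a level not well above background. IFIT1 (−1.67 ± 0.52, adjusted p = 0.0264) was not called without the block (0.485), without donor 1 (0.184), donor 2 (0.0595) or donor 3 (0.0915), with no filter on dim probes (0.0531) or with array quality weights (0.0659). CD1A fell by −0.98 ± 0.14 (1.97-fold, adjusted p = 2.07e-06, 0.466 without the block). In total 1262 genes were called, 685 higher and 577 lower. Without the block 281 were called, 201 higher and 80 lower, and without donor 1, 2, 3 and 4 the counts were 904, 920, 755 and 843.

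Several gene lists told IL-10 cells from untreated cells at 12 h. Of 22 STAT3 targets 11 were higher (13 adjusted over the list alone, adjusted p = 9.44e-10), among them SBNO2 (1.08, adjusted p = 9.52e-08) and CEBPD (1.16, 0.18 without the block). Of 29 IL-10-associated macrophage genes, 8 of them in another list, 17 were higher and 1 lower (17 and 1 adjusted over the list alone, adjusted p = 6.61e-13), with MS4A4A at 1.46 (adjusted p = 5.04e-10, 0.0768 without the block). Of 14 monocyte markers, 5 of them in another list, 6 were higher (6 adjusted over the list alone, adjusted p = 6.34e-07). S100A9 was at 2.39 (adjusted p = 1.89e-12, 0.198 without the block), S100A8 at 2.34 (adjusted p = 4.54e-11). THBS1 was at 1.81 (adjusted p = 0.00302, 0.638 without the block and 0.0666 without donor 4). Metallothioneins were higher in 6 of 7 (7 adjusted over the list alone, median 1.99, adjusted p = 3.49e-06, but adjusted p = 0.22 with an estimated correlation), with MT1E at 2.17 (adjusted p = 0.000456). Against untreated 0 min, MT1H was at −1.345 with IL-10 at 12 h and at −3.33 in untreated cells. Type I interferon-stimulated genes leaned lower (median −0.46), 2 higher and 6 lower of 33 (3 and 10 adjusted over the list alone, adjusted p = 0.0136). That list call was absent without the block (0.0929), reversed direction without donor 1 (0.107), and had adjusted p = 0.868 with an estimated correlation. IFITM2 (1.79, adjusted p = 9.73e-06) and IFITM3 (1.54, adjusted p = 0.00103, 0.201 without the block and 0.0603 without donor 2) ran against it. ISG15 (−1.24 in 3 of 4 donors, adjusted p = 0.0209) ran with it, but was not called without the block (0.496), donor 1 (0.304) or donor 3 (0.14), or with array quality weights (0.0552).

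Other lists showed mixed or no movement with IL-10 at 12 h. Dendritic cell identity genes, 4 of 16 also in another list, had 2 higher and 5 lower (2 and 6 adjusted over the list alone, list adjusted p = 0.0979). CD1C was lower by −1.34 ± 0.11 (2.53-fold, adjusted p = 8.3e-12), CD1E by −1.34 (adjusted p = 1.17e-08, 0.25 without the block) and CD1B by −0.64 (adjusted p = 5.08e-05, 0.426 without the block), while CD209 was higher by 0.56 (adjusted p = 8.17e-06). Dendritic cell maturation had 4 higher and 3 lower of 24 (4 and 5 adjusted over the list alone, list adjusted p = 0.494), with PDCD1LG2 at 0.90 (adjusted p = 0.000718, 0.199 without the block) and CD58 at −0.79 (adjusted p = 4.21e-07). NF-kB inflammatory genes had 4 of 24 lower (4 adjusted over the list alone, list adjusted p = 0.174). Immediate early genes had 4 of 14 lower (2 higher and 5 lower adjusted over the list alone, list adjusted p = 0.174), JUN by −0.58 (adjusted p = 0.00393, 0.367 without the block). Of 18 IL-4-induced myeloid genes, 10 of them in another list, 4 were higher and 1 lower (5 and 3 adjusted over the list alone, list adjusted p = 0.0999). Receptor, JAK and STAT genes had 3 of 12 higher (3 adjusted over the list alone, median −0.03 but mean 0.09, list adjusted p = 0.43). LXR targets had 3 of 10 higher (3 higher and 1 lower adjusted over the list alone, list adjusted p = 0.21), with the lipid transfer protein gene PLTP at 2.33 (5.02-fold, adjusted p = 2.55e-05). A second detected PLTP probe was only at 0.694, so the size of this difference depends on the probe. MHC class II presentation had 1 of 17 lower (0 adjusted over the list alone, list adjusted p = 0.883). Hypoxia and glycolysis had 3 of 20 higher (3 adjusted over the list alone, list adjusted p = 0.0654) and heat shock 1 of 12 (1 adjusted over the list alone, list adjusted p = 0.183). Cell cycle had 1 higher and 1 lower of 10 (the same adjusted over the list alone, list adjusted p = 0.694), and the stress response 1 and 1 of 15 (the same adjusted over the list alone, list adjusted p = 0.427). Ribosomal proteins and neutrophil markers had 0 called (0 adjusted over the list alone, list adjusted p = 0.319 and 0.659).

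IL-6 cells at 12 h could not be told from untreated cells at 12 h. SOCS3 was at 0.51 ± 0.22, BCL3 at 0.32 ± 0.12 (n = 4, adjusted p = 0.987), and CD14 at 0.41, with these signs in 4 of 4 donors. STAT3 was at 0.12, CD163 at −0.12 and CD1A at −0.11, with these signs in 3 of 4 donors. The adjusted p was 1 for all but BCL3. With limma 0 genes were called, and 437 had an unadjusted p under 0.05 where 521 would be expected by chance. With no filter on dim probes 1 gene was called, SMIM10L2A (−0.79, adjusted p = 0.00471), and 0 under every other setting. The 95% interval lay within a 2-fold difference for 10274 genes (98.7%). The STAT3 target list leaned higher (0 called, 0 adjusted over the list alone, adjusted p = 0.0434), but with adjusted p = 0.231 with an estimated correlation, 0.116 without the block, 0.178 without donor 3 and 0.126 without donor 4. Type I interferon-stimulated genes leaned lower (median −0.16, 0 called, 0 adjusted over the list alone, adjusted p = 0.0432). That call became adjusted p = 0.89 with an estimated correlation and 0.191 without the block, reversed direction without donor 1 (0.16), and had 0.0606 without donor 3.

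From 2 h on the cytokines differed directly, and at 2 h PIM1 and SOCS3 differed most. At 2 h PIM1 was 9.57-fold higher with IL-10 than with IL-6 (3.26 ± 0.27, n = 4, adjusted p = 1.19e-10) and SOCS3 8.71-fold (3.12 ± 0.22, adjusted p = 2.34e-12). DACT1 was higher by 1.81 ± 0.28 (adjusted p = 9.61e-05) and TNIP3 by 1.84 ± 0.36 (adjusted p = 0.00191, 0.0903 without the block, 0.0874 without donor 2). CFAP161 was higher by 1.58 (adjusted p = 0.00213, 0.198 without the block, 0.0694 without donor 1) and BCL3 by 0.64 (adjusted p = 0.000868, 0.908 without the block, 0.0527 without donor 2, 0.0687 without donor 3). FOXQ1 was lower with IL-10 by −1.45 ± 0.20 (2.73-fold, adjusted p = 1.78e-05), ACVR2A by −1.34 (adjusted p = 0.000384, 0.0903 without the block) and SNAI3 by −1.10 (adjusted p = 0.000142, 0.134 without the block). SPRY2 (−1.35, adjusted p = 0.00582) was not called without the block (0.832), donor 1 (0.0812) or donor 4 (0.149), and neither was AVPI1 (−1.07, adjusted p = 0.0107) without the block (0.297), donor 2 (0.0928), donor 3 (0.116) or donor 4 (0.119). Of 22 STAT3 targets 10 were higher and 1 lower (12 and 2 adjusted over the list alone, adjusted p = 2.94e-20), including GADD45B (1.42, adjusted p = 4.3e-07). In total 163 genes were called, 115 higher and 48 lower, against 22 without the block (18 higher, 4 lower), 252 with array quality weights, and 102, 78, 83 and 99 without donor 1, 2, 3 and 4. NF-kB inflammatory genes leaned toward IL-6 (0 called, 0 adjusted over the list alone, adjusted p = 0.0336), with adjusted p = 0.766 with an estimated correlation, 0.191 without donor 1 and 0.16 without donor 4. IL-10-associated macrophage genes had 4 of 29 higher (5 adjusted over the list alone, adjusted p = 2.07e-06, adjusted p = 0.0219 with an estimated correlation). Monocyte markers had 1 of 14 higher (3 adjusted over the list alone, adjusted p = 0.0432, but adjusted p = 0.325 with an estimated correlation). That call ended without the block (0.569), with the authors' processed values (0.0514), and without donor 1 (0.0712), donor 2 (0.15) or donor 3 (0.116). Cholesterol synthesis leaned toward IL-6 (0 called, 0 adjusted over the list alone, adjusted p = 0.0233), with adjusted p = 0.428 with an estimated correlation, 0.0599 without the block and 0.117 without donor 2.

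At 4 h and 8 h the direct difference took in FPR1, VCAN and TNIP3. With IL-10 against IL-6 at 4 h TNIP3 was higher by 3.26 ± 0.36 (n = 4, adjusted p = 3.61e-08), being detected on 1 of 4 arrays with IL-6, and the nuclear lamina gene LMNB1 by 2.41 (5.33-fold, adjusted p = 2.22e-09). VCAN was higher by 2.24 (4.72-fold, adjusted p = 1.56e-07), FPR1 by 2.22 (adjusted p = 3.31e-08, 0.0783 without the block) and SLC1A3 by 2.12 (adjusted p = 6.68e-07). ADORA3 (−1.56, adjusted p = 9.07e-07), PPARGC1B (−1.54, adjusted p = 5.11e-06), LFNG (−1.46, adjusted p = 2.44e-07), TIMP3 (−1.47, 0.442 without the block) and RAPH1 (−1.20, adjusted p = 8.19e-07, 0.0583 without the block) were lower. SOCS3 differed by 2.06 at 4 h (adjusted p = 3.03e-08), STAT3 by 0.69 (adjusted p = 9.78e-05), BCL3 by 0.84 (0.133 without the block) and CD163 by 0.67 (adjusted p = 0.000974, 0.933 without the block). At 8 h TNIP3 was higher at least 4.40-fold (3.03, adjusted p = 2.11e-07), CEMIP at least 2.35-fold (2.45, adjusted p = 0.00229, 0.0674 without donor 2) and ARNT2 at least 2.45-fold (2.29, adjusted p = 1.14e-05), all not well above background with IL-6. FPR1 (2.83, adjusted p = 1.91e-10), VCAN (2.76, adjusted p = 2.34e-09), SOCS3 (2.01, adjusted p = 7.58e-08) and CD163 (1.21, adjusted p = 8.53e-08, 0.83 without the block) were higher. IFNLR1 (−1.41, adjusted p = 0.000248, but a log2 difference of 0.018 on a second detected probe) and ADORA2B (−1.27, adjusted p = 3.78e-05, 0.0568 without the block) were lower. TIMP3 (−1.39, 0.613 without the block, 0.0828 without donor 2), LY9 (−1.28, adjusted p = 0.00245, 0.624 without the block, 0.0802 without donor 4) and CLDN1 (−1.72, adjusted p = 0.033) were lower too. CLDN1 was called neither without the block (0.936) nor without donor 1, 2, 3 or 4 (0.108, 0.0615, 0.145 and 0.088), nor with no filter on dim probes (0.0663). The counts were 686 at 4 h (405 higher, 281 lower; 174 without the block, 139 and 35; 405, 439, 450 and 467 without donor 1, 2, 3 and 4). At 8 h there were 612 (365 higher, 247 lower; 88 without the block, 78 and 10; 418, 390, 339 and 391 without those donors).

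At 12 h DHRS2, OLFML2B, FPR1 and CD163 were higher with IL-10 than with IL-6. DHRS2 differed by 2.89 (7.39-fold, n = 4, adjusted p = 1.23e-10, 0.38 without the block) and OLFML2B by 2.65 (adjusted p = 7.75e-10). FPR1 was higher by 2.63 (adjusted p = 6.05e-10) and VCAN by 2.51 (adjusted p = 9.09e-09). ARNT2 was higher at least 3.13-fold (2.57, adjusted p = 1.23e-06) and CEMIP at least 2.48-fold (2.57, adjusted p = 0.00113), from levels not well above background with IL-6. CD163 was higher by 1.77 ± 0.14 (3.42-fold, adjusted p = 6.11e-12, 0.408 without the block), CD14 by 1.01 (adjusted p = 0.00193, 0.776 without the block) and SOCS3 by 1.55 (2.92-fold, adjusted p = 7.42e-06). CLDN1 (−3.03, adjusted p = 7.03e-05, 0.451 without the block), CD1C (−1.18, adjusted p = 3.79e-10, 0.0941 without the block) and CD1A (−0.87, adjusted p = 3.35e-05, 0.7 without the block) were lower. CLEC5A (−1.88, at least 1.94-fold, adjusted p = 0.00305) was not called without the block (0.137), donor 3 (0.0603) or donor 4 (0.0527). HBEGF (−1.72, adjusted p = 0.0232) was not called without the block (0.38), donor 1 (0.0739), donor 2 (0.128) or donor 4 (0.0643). GAL (−1.64) was not called without the block (0.567) or donor 2 (0.0575), and TIMP3 (−1.46) without the block (0.45) or donor 2 (0.0609). In total 831 genes were called, 481 higher and 350 lower, against 121 without the block (96 higher, 25 lower) and 624, 546, 506 and 545 without donor 1, 2, 3 and 4.

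In the direct comparison at 12 h STAT3 targets had 9 higher of 22 (13 higher and 1 lower adjusted over the list alone, adjusted p = 3.15e-09). IL-10-associated macrophage genes had 16 of 29 higher (17 higher and 1 lower adjusted over the list alone, adjusted p = 2.65e-13). Monocyte markers had 6 of 14 higher (6 adjusted over the list alone, adjusted p = 7.7e-09). Metallothioneins had 6 of 7 higher (6 adjusted over the list alone, adjusted p = 4.64e-06, but adjusted p = 0.226 with an estimated correlation). Heat shock genes had 2 of 12 higher (2 adjusted over the list alone, adjusted p = 0.00846), with 0.102 without donor 3 and adjusted p = 0.376 with an estimated correlation. Dendritic cell identity genes leaned lower, 2 higher and 4 lower (2 and 5 adjusted over the list alone, adjusted p = 0.0302). That call ended without the block (0.552) and without donor 1 (0.0594), donor 2 (0.0988) or donor 3 (0.0921), and had adjusted p = 0.22 with an estimated correlation.

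The gap between IL-10 and IL-6 changed from the early times (45 min and 2 h) to the late ones (8 h and 12 h) for 422 genes, 252 upward and 170 downward. ARNT2 gained 2.43 (n = 4, adjusted p = 6.73e-06) and VCAN 2.13 (adjusted p = 8.35e-07). DHRS2 gained 2.18 (adjusted p = 2.11e-07, 0.929 without the block), OLFML2B 2.07 (adjusted p = 5.89e-07, 0.228 without the block). CD163 gained 1.33 (adjusted p = 2.43e-08, 0.951 without the block) and CEMIP 2.48 (adjusted p = 0.00307, 0.0518 without the block, 0.0924 without donor 2, 0.0522 without donor 3). STAT3 gained 0.49 (adjusted p = 0.00849, 0.362 without the block, 0.128 without donor 3, 0.224 without donor 4), and SOCS3 was at −0.08 (below 0 in 3 of 4 donors, adjusted p = 0.943). That SOCS3 value averaged unlike early gaps, 0.59 at 45 min and 3.12 at 2 h, against 2.005 at 8 h and 1.55 at 12 h. It therefore does not mean that the SOCS3 gap was constant over time. CLDN1 (−2.41, adjusted p = 0.00232, 0.945 without the block), IFNLR1 (−1.44, adjusted p = 0.000326, 0.0682 without the block, but a log2 value of −0.299 on a second detected probe) and GAL (−1.61, adjusted p = 0.014, 0.886 without the block, 0.0691 without donor 1, 0.0957 without donor 2) moved the other way. HCAR3 (−1.35, adjusted p = 0.000872, 0.366 without the block) and HCAR2 (−1.29, adjusted p = 0.00479, 0.415 without the block, 0.17 without donor 2, 0.0944 without donor 3) did too, though probes of this pair of near-identical genes may cross-hybridise. The count was 25 without the block (25 upward, 0 downward) and 276, 234, 177 and 230 without donor 1, 2, 3 and 4. Monocyte markers gained in 5 of 14 (6 adjusted over the list alone, adjusted p = 6.01e-09) and IL-10-associated macrophage genes in 8 of 29 (13 adjusted over the list alone, adjusted p = 4.45e-10).

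**Figure D4:**
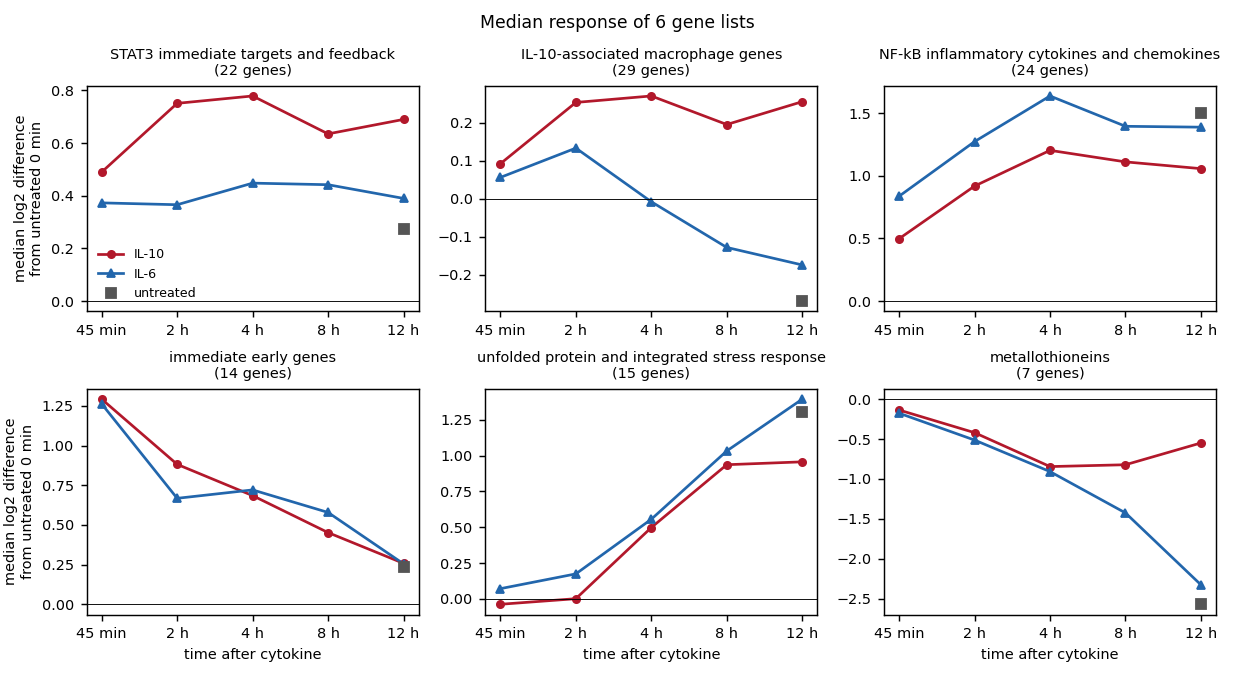
Median log2 difference from untreated 0 min (vertical axis) of 6 gene lists against time (horizontal axis, evenly spaced) for IL-10 (red circles), IL-6 (blue triangles) and untreated cells at 12 h (square). Lists hold 7 to 29 genes; metallothioneins had a median of −2.57 in untreated cells at 12 h.

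Too few genes were measured to test T cell markers (1 of 13), NK cell markers (3 of 10), B cell markers (2 of 10), platelet markers (3 of 9) and erythroid markers (2 of 8). Between IL-10 at 12 h and untreated 12 h, GZMB was at 1.35 (n = 4, adjusted p = 0.0251), a value not followed with donors left out. The others were at 0.22 for CD2, 0.19 for KLRF1, 0.12 for KLRB1, 0.01 for CD79A, 0.35 for CD79B, −0.19 for PPBP, 0.51 for ITGB3, −0.14 for TREML1, 0.36 for HBA2 and −0.19 for AHSP. Across all 21 lists and 19 comparisons 120 of 399 list tests were called, 109 toward higher and 11 toward lower, and 53 with an estimated correlation.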

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

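Of the tests in this part, those of array position, of handling at 45 min and of monocyte content were chosen only after the result was seen, and that of dim genes was chosen before. A single donor far from the other 3 was found in 17 of 355 sets of gene differences, and chance alone gives about 1 in 20. Donor 1 was the one apart in 10 of the 17, donor 2 in 3, donor 3 in 0 and donor 4 in 4.

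Among early differences from untreated 0 min, the donor apart had 3.814 for GADD45B with IL-10 at 45 min (others 3.254 to 3.288), −1.053 for CLK1 (others −1.217 to −1.189) and 2.096 for NFKBIZ with IL-6 at 45 min (others 3.394 to 3.646). IL10RA with IL-6 at 2 h had 0.113 (others 0.227 to 0.242). At 4 h BCL3 with IL-10 had 1.299 (others 2.023 to 2.163) and SOCS3 with IL-6 had 1.855 (others 1.167 to 1.271). Against the same baseline at 12 h, SLC16A10 with IL-10 had 2.387 (others 4.287 to 4.592). With IL-6 at 12 h, MT1G had −0.267 (others −3.469 to −3.232), STAT3 0.908 (others 0.239 to 0.278) and CD1A −0.705 (others −0.158 to −0.128). MT1F in untreated cells had −1.076 (others −2.823 to −2.773).

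Between IL-10 and untreated cells at 12 h the donor apart had −0.03 for CLEC5A (others −2.819 to −2.51), −4.394 for IFIT1 (others −1.078 to −0.5) and −1.027 for IFNLR1 (others −1.862 to −1.798). Between IL-10 and IL-6, PIM1 at 2 h had 2.699 (others 3.367 to 3.503). At 12 h FPR1 had 1.911 (others 2.841 to 2.89) and CLEC5A −0.037 (others −2.649 to −2.353). Among 12 groups of arrays tested in the same way, 1 sample with IL-10 at 45 min had 15153 detected probes, where the other 3 had 14304 to 14393.

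The gap between IL-10 and IL-6 differed between late and early times, by a test of the difference itself, for 422 genes. The genes named were CEMIP (2.479), ARNT2 (2.434), DHRS2 (2.176), VCAN (2.134), OLFML2B (2.067), CLDN1 (−2.414), GAL (−1.614), IFNLR1 (−1.44, but −0.299 on a second detected probe), HCAR3 (−1.35) and HCAR2 (−1.291). Outside the genes analysed, 140 of 3650 detected probes without a gene name were called between IL-10 and untreated cells at 12 h, 80 higher and 60 lower, and 0 between IL-6 and untreated cells.

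The broad change between 0 min and 12 h was set against array position, because each group sat at 1 position. The count of genes called between 2 groups did not follow their distance on the chip over 66 pairs (Spearman rho −0.00949, 1-sided permutation p = 0.451 from 10000 permutations), while it followed their difference in time with rho 0.734. The first position alone, which held untreated 0 min, is not needed, since IL-6 at 12 h against IL-6 at 45 min called 3273 genes. Fewer detected probes at late times would place the calls among dim genes, but 41.1% of the brightest 3471 genes were called between untreated 12 h and 0 min, against 21.5% of the dimmest 3471. These values argue against 3 narrow explanations: a smooth gradient along the chip, the first position alone, and calls confined to dim genes. The share of bright genes called does not address a technical cause that also acts on bright genes. Effects particular to other single positions were not tested, since position and group remain confounded. An effect of time in culture fits the design but was not separated from these.

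Immediate early and inflammatory genes that rose at 45 min under both cytokines could reflect the handling of the cultures when cytokine was added. For the 18 such genes the median IL-10 minus IL-6 difference at 2 h was −0.0639, with donor medians from −0.152 to 0.205, and only ZFP36 was called (0.73). The other 6 genes of the STAT3 list called at 45 min had a median of 1.03 in favour of IL-10. A median near 0 is what handling would give, and also what signalling shared by both cytokines would give, so the test cannot tell. Untreated cells at 45 min are not among the samples.

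Higher monocyte markers with IL-10 at 12 h could come from more monocytes in those cultures. Of 12 markers expressed at or below the baseline of the called ones, 4 (FCN1, CSF3R, MNDA and CLEC4E) had a 95% interval wholly under a 1.5-fold rise. CLEC4E lay below the lowest detected signals of the untreated 12 h arrays, and levels of different probes are not directly comparable, so this count excludes nothing. FCN1 was at −0.14 and CSF3R at −0.05, while S100A9 was at 2.39 and VCAN at 3.11. More monocytes and regulation of some of these genes by IL-10 cannot be told apart here.

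The 8 samples of each comparison were divided into 4 and 4 in all 35 ways, most of which ignore the pairing by donor. For the 16 pairs of groups with calls the real split ranked 1 of 35. Against untreated 0 min the highest other splits called 30, 159, 810, 1110 and 790 genes for IL-10 at the 5 times, 7, 152, 787, 1016 and 1210 for IL-6, and 1251 for untreated cells. The real values were 140, 1966, 3548, 3887 and 3386 for IL-10, 105, 1218, 2412, 3362 and 3438 for IL-6, and 3532. At 12 h against untreated cells IL-10 called 1262 and the highest other split 222. Between the cytokines at 2 h to 12 h the real values were 163, 686, 612 and 831, and the highest others 4, 17, 15 and 94. Among the 8 splits that part the samples of every donor, the highest others were 1, 60, 375, 752 and 552 for IL-10, 0, 9, 326, 1016 and 1210 for IL-6, 1251 for untreated cells, 21 for IL-10 at 12 h, and 0, 2, 0 and 2 between the cytokines. The real split called the most genes of these 8 too, but a rank of 1 of 8 alone does not exclude chance. The late against early gap, with 559 genes when fitted to gaps within donors, ranked 1 of 100, with 7 as the highest other. With 0 calls in the real split, IL-6 against untreated cells at 12 h (highest other 190) and the cytokines at 45 min (highest other 2) ranked 35 of 35. A count of 0 is matched by every split, so the ranking tests nothing there.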

How the results depend on the processing

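Array quality weights were chosen after the data were seen; the other settings were fixed before. All 972 called differences of genes taken by the naming rule kept their direction under every setting. Of these, 963 stayed called with normexp and quantile normalization, 952 with the authors' processed values, 902 with no filter on dim probes, 951 with array quality weights and 956 of 956 with the stricter filter. Without the donor block 527 stayed called, and 853, 767, 810 and 822 did so without donor 1, 2, 3 and 4, where fewer samples lower the power.

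Without the donor block every non-zero count of called genes moved, because differences between donors then enter the error. Against untreated 0 min the counts became 42, 939, 1966, 2156 and 1687 for IL-10 at 45 min, 2 h, 4 h, 8 h and 12 h, 40, 478, 969, 1640 and 1763 for IL-6, and 1809 for untreated cells. IL-10 against untreated cells at 12 h became 281, IL-10 against IL-6 at 2 h, 4 h, 8 h and 12 h became 22, 174, 88 and 121, and the late against early gap became 25. The genes shared by IL-6 and IL-10 became 34, 400, 793, 1235 and 1104 at the 5 times. Among the lists and the genes under the naming rule, it changed no call given in the report other than those with a value without the block beside them.

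With a donor left out, counts against untreated 0 min ranged over 54 to 87, 1293 to 1507, 2592 to 3005, 2722 to 3541 and 2349 to 2873 for IL-10, over 50 to 72, 666 to 943, 1339 to 2166, 2267 to 3190 and 2161 to 3338 for IL-6, and over 2246 to 3357 for untreated cells. IL-10 against untreated cells at 12 h ranged from 755 to 920, the direct comparisons over 78 to 102, 405 to 467, 339 to 418 and 506 to 624, and the late against early gap from 177 to 276. The shared genes ranged over 45 to 62, 539 to 758, 1083 to 1700, 1698 to 2416 and 1375 to 2056. Both counts of 0 stayed 0.

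IL-6 against untreated cells at 12 h called 1 gene with no filter on dim probes, SMIM10L2A, which was named after its value was seen, and the cause was not tested. IL-10 against IL-6 at 2 h called 252 genes with array quality weights, and the cause was not tested. List calls fell from 120 to 53 with an estimated correlation, which allows for genes of a list varying together. They were 105 without the block, 125 with normexp and quantile normalization, 124 with the authors' processed values and 105 to 134 with a donor left out. Of the 120, 101 stayed called without the block, 120 and 119 with the other normalizations, and 106, 107, 101 and 116 without donor 1, 2, 3 and 4.

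The test of type I interferon-stimulated genes in IL-10 12 h vs untreated 12 h reversed without donor 1 (adjusted p = 0.107, range 3.76e-05 to 0.107 over donors left out). The test of type I interferon-stimulated genes in IL-6 12 h vs untreated 12 h did so too (adjusted p = 0.16, range 0.000942 to 0.16), and the cause was not tested. Small uncalled differences reversed too, and the cause was not tested. IL10RA with IL-10 against untreated 12 h was −0.024 without donor 4 (range to 0.122), and IL6ST was 0.003 without donor 1 (range from −0.202). STAT3 between the cytokines at 45 min was −0.051 without donor 2 (range to 0.179) and −0.022 with array quality weights. SOCS3 in the late against early gap was 0.193 without donor 2 (range from −0.409) and 0.07 with array quality weights. Of 102 uncalled differences of genes under the naming rule, 39 changed sign in at least 1 setting, the largest of them 0.201 with all donors, and 4 became called in at least 1. The chip as a random block was not run, since chip and donor are the same. Signal over background limits the genes at least N-fold apart, whose dim group gives only a bound.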

Other observations

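The test of opposition below was chosen before its result was seen. A glucose metabolism gene separated the cytokines early. At 2 h PFKFB3, which drives glycolysis, rose with IL-10 by 2.46 (n = 4 donors), and between the cytokines it was 1.29 higher with IL-10 (adjusted p = 1.95e-05, 0.245 without the block). The induced transporter gene SLC1A3 was still 1.75 above untreated cells at 12 h with IL-10 (adjusted p = 8.51e-06), NAMPT was 0.86 above (adjusted p = 0.00614) and TUBB3 1.18 above (adjusted p = 7.22e-05).

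SREBF1, a regulator of fatty acid synthesis, was 0.69 higher with IL-10 than in untreated cells at 12 h (n = 4 donors, adjusted p = 1.2e-06). Cholesterol synthesis genes rose at 4 h under both cytokines, 9 of 14 with IL-6 (9 adjusted over the list alone, adjusted p = 6.83e-08, adjusted p = 0.0203 with an estimated correlation) and 8 with IL-10 (8 adjusted over the list alone, adjusted p = 6.92e-05, adjusted p = 0.105 with an estimated correlation). INSIG1 rose by 2.18 with IL-6 (adjusted p = 6.54e-11) and 2.01 with IL-10 (adjusted p = 5.4e-11). MCM5, of DNA replication, was 1.28 higher with IL-10 than in untreated cells at 12 h (adjusted p = 4.13e-08).

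IL-10 may oppose part of the change that the cells undergo in culture. Genes called between IL-6 at 12 h and untreated 0 min were compared with those called between IL-10 and untreated cells at 12 h, which share no array. Of 650 genes called in both, 66% went opposite ways, 63.1% to 65.7% when single donors were used. The single donors were taken on the same genes, chosen with all donors, so their range is not independent replication. Of the 650 genes 226 rose in culture and were lower with IL-10, such as CLDN1, and 203 fell and were higher, such as CD14, while 128 and 93 went the same way. Across genes, which are not independent replicates, the differences correlated with r = −0.198. The values fit opposition for a majority of shared genes and do not describe the rest.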
